A study of Solanum tuberosum with 24 samples.

How the data were processed

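Gene-level RNA-seq values were read for 24 potato tuber libraries, which the labels place in 4 cultivars at an early stage and at the peak of powdery scab infection, with 3 libraries in each of the 8 groups. The labels call Huangxin 226 and BF017 highly susceptible and Zhongshuhong 3 and Zhongshuzao 47 highly resistant. They do not say whether the 3 libraries of a group came from separate tubers or plants, so p-values measure only the spread between these samples, which may be technical. Uninfected tubers, sampling dates and sequencing batches were not given in the sources used here.

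The authors deposited a table of counts per gene that are estimated counts, not whole reads: between 28.1 and 30.3% of the values above 0 in a library were not whole numbers, and columns summed to between 15108237 and 23298525. A matching deposited table gave TPM, which are also scaled for gene length. Per the labels' protocols, RNA was extracted with TRIzol, and the library step they describe is of a small RNA type, although the deposited values cover whole gene models. The aligner, counting tool and genome build were not given in the sources used here, and no coordinates are printed. Each deposited table held 48915 genes, of which 39021 carried PGSC identifiers of the potato reference, 8579 MSTRG identifiers of assembled loci and 1315 identifiers of noncoding RNA. Names were taken from the annotation columns of the same tables, with a description for 40333 genes, a KEGG orthologue (KO) for 13545 and Gene Ontology terms for 32601. Each table also held 8 columns with the authors' group means, which were not used.

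The estimated counts were rounded to whole numbers for the count tests. The design fixed before the data were examined had assumed whole counts, and its test was kept. Genes with low counts were removed by edgeR's filterByExpr (minimum count 10), which left 25833 genes holding at least 99.902% of each library's counts. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model over the 8 groups, so that all libraries shared 1 estimate of the spread (common biological coefficient of variation 25.5%). Resistant and susceptible cultivars were compared at each stage as the mean of 2 cultivars minus the mean of the other 2. Peak and early stages were compared within each cultivar and on average, and the interaction was the change in the resistant minus that in the susceptible cultivars. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in either direction. Because libraries of a cultivar are not independent cultivars, genes are also counted that passed on average and had the same sign and an adjusted p under 0.05 in all 4 resistant-susceptible cultivar pairs, or in all 4 cultivars for the stage comparison. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All adjusted p-values of single genes are from edgeR unless another tool is named.

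Levels are CPM on TMM-scaled library sizes. A gene with 0 counts in a library can have had up to between 0.13 and 0.205 CPM there, the level of 3 counts. Such floors cover counting error only, since PCR copies are not independent molecules. For genes with 3 or fewer counts in a group compared, the report gives levels without a fold, because a fitted fold then depends on the prior count, as it does where the closing section prints one. Copies of gene families with similar sequence (patatins, phenylalanine ammonia-lyases, chalcone synthases, endochitinases, subtilases, protease inhibitors and small heat shock proteins) may share reads in estimated counts, so the values of single copies are uncertain. Overlapping and antisense genes may share reads too, as the use of strand was not given in the sources used here.

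Gene lists were fixed before the data were examined, from KO identifiers or words in the annotation. They covered monolignol biosynthesis, laccases with class III peroxidases and dirigent proteins, suberin and wax, flavonoids and anthocyanins, pathogenesis-related proteins, pattern-triggered signalling, NLR and other annotated disease resistance proteins, salicylic acid signalling, jasmonate, ethylene, WRKY factors, MYB factors, starch, sucrose transport and cleavage, patatins, protease inhibitors, photosynthesis, cell division, cell wall remodelling, heat shock proteins, steroidal glycoalkaloids, xylem and phloem. Sets were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), with camera using an estimated correlation, and with fry, adjusted over the lists within a comparison. Lists with fewer than 5 tested genes were reported by gene. Genes to name were chosen by a rule fixed before the data were examined: the 10 highest and 10 lowest log2 changes among genes with an informative entry in the description column (assembled loci had none) that passed in all 4 pairs or cultivars with a mean of at least 1 CPM (5 and 5 passing genes for the interaction). From each list the 2 members with the largest change among those passing all 4 pairs were added, or failing that those passing on average, or failing that the member with the highest level, and the most abundant member of each KO of monolignol biosynthesis.

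The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. With the fold threshold, the resistant-susceptible comparison at the early stage recovered 34% of the 2-fold and 84% of the 4-fold changes among 24723 genes, the average stage comparison 40 and 93% among 24779 and the interaction 27 and 71% among 24738. Replicate libraries of a group differed by far more than counting noise, with a chi-square per gene of at least 17.1 for each pair, so none was treated as deposited more than once.

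Alternatives were other scalings and filters, DESeq2, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a stricter p, no fold threshold, fits on 1 stage, on 1 cultivar or with the classes only, a replicate block, and leaving out each library and each cultivar. Restriction to reference gene models and leaving out cultivars in the average stage comparison were chosen after seeing the data, as were the enrichment of Gene Ontology terms and the clock gene lists.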

Results

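Tuber RNA was profiled in 24 libraries from 4 potato (Solanum tuberosum) cultivars, with 3 libraries per cultivar at an early stage and 3 at the peak of powdery scab, a tuber disease caused by the soil-borne protist Spongospora subterranea. Zhongshuhong 3 and Zhongshuzao 47 are described as highly resistant, Huangxin 226 and BF017 as highly susceptible. Levels of a gene are given as mean CPM (counts scaled to library size) of 3 libraries, and where 4 levels follow each other without names they belong to Zhongshuhong 3, Zhongshuzao 47, Huangxin 226 and BF017 in that order. Library totals ran from 15108237 to 23298525 estimated counts, and the 10 most abundant genes took between 6.599 and 20.55% of a library. Tubers without infection were not analysed here, so each difference is between cultivars or between stages of infected material.

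Each of the 24 libraries correlated best with a library of its own cultivar and stage (Pearson r of log2 CPM across genes between 0.955 and 0.98 within groups). Libraries of a cultivar at its other stage had a median r of 0.92, against 0.89 for the other cultivar of the same class and 0.889 for a cultivar of the other class at the same stage. These correlations are across genes, which are not independent replicates.

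**Figure D1:**
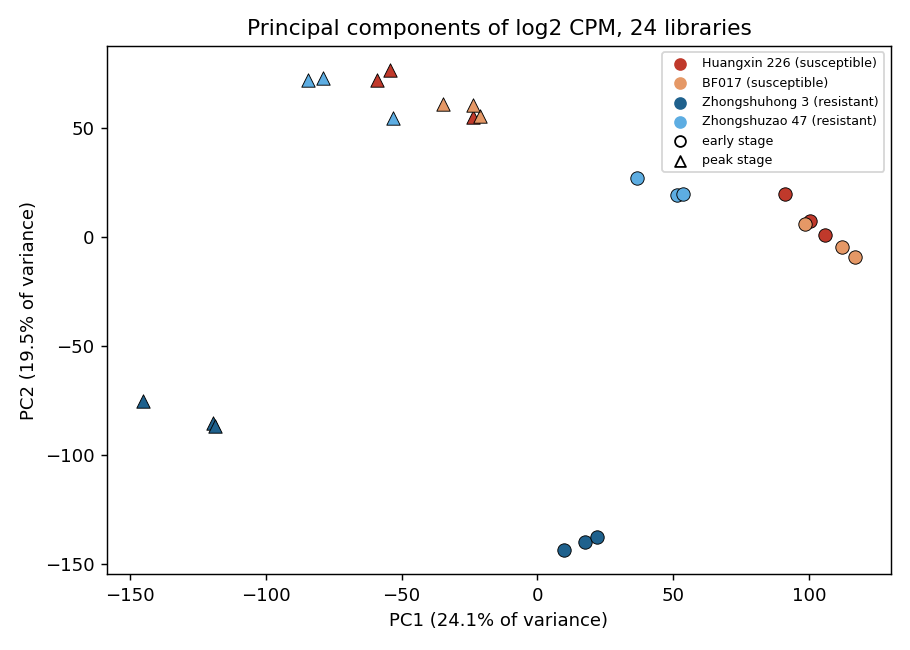
Position of the 24 libraries on the first and second principal components of log2 CPM (axes in arbitrary component units, with 24.1 and 19.5% of the variance). Colours give the cultivar, circles the early and triangles the peak stage; the 6 libraries of Zhongshuhong 3 lie apart from the other 18 on the second component.

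The first comparison asked which transcripts differed between resistant and susceptible tubers early in infection. Phenylalanine ammonia-lyase copy PGSC0003DMG401021549, which opens phenylpropanoid metabolism, was higher in the resistant cultivars (2.50 ± 0.37 on the log2 scale, ± SE). It passed in all 4 resistant-susceptible cultivar pairs, with 2889, 710.3, 226 and 284 CPM. Copy PGSC0003DMG402021549 reached 16101 ± 6176 CPM (mean ± SD, n = 3) in Zhongshuhong 3 and 2593, 964 and 2132 in the others. It passed on average (2.17 ± 0.34), not in all 4 pairs. Small heat shock protein Hsp20.1 (PGSC0003DMG400017098, -4.85 ± 0.53) and Hsp70 (PGSC0003DMG400011197, -3.15 ± 0.47), which are chaperones, and probable pectate lyase 5 (PGSC0003DMG400010771, -1.93 ± 0.34), a pectin-degrading enzyme, were lower in the resistant cultivars. Across all genes, 1925 were higher and 1750 lower, 3675 of 25833 tested. Of them 484 and 365 passed with the same sign in all 4 pairs.

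Among 60 tested genes of monolignol biosynthesis, the pathway of lignin precursors, 11 were higher and 7 lower, and the list did not pass as a set (camera adjusted p = 0.56). Caffeic acid O-methyltransferase II (PGSC0003DMG400013342), at 0.0562 and 0.377 CPM against 3.09 and 3.81, was lower, and caffeoylshikimate esterase (PGSC0003DMG400005611) differed by -1.21 ± 0.16, both in all 4 pairs. The most abundant gene of the other steps did not pass for cinnamate 4-hydroxylase (PGSC0003DMG402030469, -0.20 ± 0.15), 4-coumarate:CoA ligase (PGSC0003DMG400003155, 1.02 ± 0.44), p-coumaroyl quinate/shikimate hydroxylase (PGSC0003DMG400007178, -0.33 ± 0.32), cinnamoyl-CoA reductase (PGSC0003DMG400028521, 0.04 ± 0.43), ferulate-5-hydroxylase (PGSC0003DMG400003546, -0.77 ± 0.47), caffeic acid O-methyltransferase (PGSC0003DMG400000560, -1.04 ± 0.58) and cinnamyl alcohol dehydrogenase (PGSC0003DMG400005001, 0.37 ± 0.08). The hydroxycinnamoyltransferase orthologue with the highest level (PGSC0003DMG400016095), described as an anthocyanin acyltransferase, held 938, 0.0814, 4.803 and 0.961 CPM and did not pass (adjusted p = 0.37). The caffeoyl-CoA O-methyltransferase orthologue (PGSC0003DMG400006448), whose protein match is a flavonoid methyltransferase, held 2151, 0.425, 6.62 and 1.54 CPM and was higher on average (adjusted p = 0.0015).

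Among genes of anthocyanin synthesis, the pathway of red and purple pigments, anthocyanin synthase (PGSC0003DMG400022746) held 594, 0.401, 1.55 and 1.07 CPM (3.60 ± 0.43), flavonoid 3',5'-hydroxylase (PGSC0003DMG400000425) 800.4, 0.626, 4.65 and 1.397 (3.15 ± 0.62), and the MYB gene PGSC0003DMG400030548 27.6, 0.172, 0.267 and 0.261 (3.06 ± 0.49), each higher on average. For flavonoid and anthocyanin genes 6 of 13 were higher and 3 lower (camera adjusted p = 0.45), none in all 4 pairs. Without Zhongshuhong 3 the signs turned for anthocyanin synthase (-1.66), the hydroxylase (-2.01) and the methyltransferase (-2.89).

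Lists of cell division, heat shock and cell wall remodelling genes were lower in the resistant cultivars by camera with a preset correlation. For cell division 0 of 69 were higher and 6 lower (adjusted p = 0.026, adjusted p = 0.91 with an estimated correlation). Among them were cyclin D3;3 (PGSC0003DMG401015433, -1.65 ± 0.25) and a histone H2A gene (PGSC0003DMG400021806, -1.39 ± 0.12). For heat shock proteins 0 of 77 were higher and 11 lower (adjusted p = 0.026, adjusted p = 0.91 with an estimated correlation). For cell wall remodelling 2 of 62 were higher and 16 lower (adjusted p = 0.037, adjusted p = 0.91 with an estimated correlation). Among them was xyloglucan endotransglucosylase/hydrolase 12 (PGSC0003DMG400003866, -1.13 ± 0.19). Photosynthesis genes, the marker of green tissue, did not pass as a set (0 of 66 were higher and 5 lower, median -0.22, adjusted p = 0.086), with -3.21 ± 0.64 for a Rubisco small chain (PGSC0003DMG400012666) and -2.57 ± 0.33 for oxygen-evolving enhancer protein 2 (PGSC0003DMG400031395).

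The remaining lists did not pass as sets by camera. By fry, which does not compare a list with other genes, suberin and flavonoid genes did. For laccases, class III peroxidases and dirigent proteins 1 of 49 were higher and 5 lower (camera adjusted p = 0.56). Among them was a lignin-forming anionic peroxidase (PGSC0003DMG400032147, -2.71 ± 0.45). For suberin and wax, the periderm marker, 0 of 9 were higher and 2 lower (adjusted p = 0.38). 3-ketoacyl-CoA synthase 11 (PGSC0003DMG400007373) stood at -1.43 ± 0.21. For pathogenesis-related proteins 3 of 55 were higher and 4 lower (adjusted p = 0.56), with a glucan endo-1,3-beta-glucosidase (PGSC0003DMG400029596) at -1.54 ± 0.17. For pattern-triggered signalling 8 of 132 were higher and 4 lower (adjusted p = 0.83). Examples were an Xa21-like receptor kinase (PGSC0003DMG400023614, -1.65 ± 0.23) and the oxidase homologue RBOHD (MSTRG.23596, -1.24 ± 0.19). For NLR and other resistance proteins 16 of 245 were higher and 24 lower (adjusted p = 0.83), with PGSC0003DMG401029995 at -1.20 ± 0.16 and PGSC0003DMG401006653 at -1.05 ± 0.16.

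Hormone lists held few passing genes. For jasmonate 2 of 38 were higher and 1 lower (adjusted p = 0.83), with a 13S-lipoxygenase (PGSC0003DMG400032155) at 10.2, 4.28, 0 and 14.5 CPM, higher in the fitted log2 average, and 12-oxophytodienoate reductase 1 (MSTRG.22996) at -1.43 ± 0.28. For ethylene 1 of 31 were higher and 1 lower (adjusted p = 0.87), the lower being an ACC synthase 4 gene (PGSC0003DMG400033885, -1.43 ± 0.22). For salicylic acid signalling 0 of 19 were higher and 0 lower (adjusted p = 0.64; 5 at an unadjusted p under 0.05 by edgeR, 0 called by DESeq2). Its most abundant member TGA7 (PGSC0003DMG400016951) differed by 0.04 ± 0.24. For WRKY factors 1 of 42 were higher and 1 lower (adjusted p = 0.58), with PGSC0003DMG401010558 at -1.46 ± 0.25. For MYB factors 1 of 60 were higher and 2 lower (adjusted p = 0.8). For starch 5 of 28 were higher and 1 lower (adjusted p = 0.58), led by the starch phosphorylase genes PGSC0003DMG400007782 (1.62 ± 0.36) and PGSC0003DMG400002479 (1.54 ± 0.35). For sucrose transport and cleavage 3 of 34 were higher and 2 lower (adjusted p = 0.83), with a sucrose synthase-like gene (MSTRG.18928) at 2.32 ± 0.30. For patatins, the storage parenchyma marker, 9 of 18 were higher and 2 lower (adjusted p = 0.55), yet patatin-like MSTRG.19611 (0.0566 and 0.0167 CPM against 1.83 and 0.499) and patatin B2 (PGSC0003DMG400008357, -1.80 ± 0.37) were lower. For protease inhibitors 4 of 39 were higher and 8 lower (adjusted p = 0.56). Serine protease inhibitor 5 (MSTRG.1852) held 39.1, 0.266, 5.598 and 111 CPM (-2.95 ± 0.72), and a serpin (PGSC0003DMG400018930) stood at -2.49 ± 0.83. Of 4 steroidal glycoalkaloid genes a solanidine glycosyltransferase (PGSC0003DMG400011749) was lower (-1.39 ± 0.35), at 3.08, 4.65, 32.8 and 2.99 CPM. No xylem (adjusted p = 0.66) or phloem gene passed by edgeR or DESeq2 (2 of 5 and 0 of 4 at an unadjusted p under 0.05 by edgeR), with xylem serine proteinase 1 (PGSC0003DMG400027892) at -0.58 ± 0.20 and a phloem protein 2-like gene (MSTRG.11914) at -0.56 ± 0.27.

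The largest early differences among genes with a deposited description, which assembled loci lack, are given as levels in the resistant against the susceptible cultivars. Raffinose synthase 2 (PGSC0003DMG400037864), an enzyme of raffinose synthesis, held 3.71 and 5.35 CPM against 0.0196 and 0.0205, the glycosyltransferase UGT90A7 (PGSC0003DMG400006949) 3.15 and 1.48 CPM against 0 and 0.0205, and the 70 kDa subunit of replication protein A (PGSC0003DMG400023096), which binds single-stranded DNA, 10.8 and 24.4 CPM against 0.01599 and 0.717. Higher as well were a cytochrome P450 (PGSC0003DMG400000534, 4.02 and 5.89 CPM against 0 and 0.5101), a dioxygenase annotated as leucoanthocyanidin dioxygenase (PGSC0003DMG400003091, 2.15 and 1.897 CPM against 0.107 and 0), a helicase (PGSC0003DMG400027503, 7.53 and 6.42 CPM against 0.536 and 0.0144) and a tRNA-dihydrouridine synthase (PGSC0003DMG400027934, 7.69 and 12.1 CPM against 1.29 and 0.0315). A reverse transcriptase (PGSC0003DMG401013133, 2.61 and 5.76 CPM against 0 and 0.119) and the transposon genes PGSC0003DMG400010915 (6.32 and 2.01 CPM against 0.144 and 0) and PGSC0003DMG400047274 (5.36 and 0.09797 CPM against 0 and 0) were also higher. Lower were a Ulp1 protease gene (PGSC0003DMG400025964, 0 and 0 CPM against 4.403 and 3.201), a PWWP-domain oxidoreductase (PGSC0003DMG400022663, 0 and 1.41 CPM against 23.4 and 7.28), a short-chain alcohol dehydrogenase (PGSC0003DMG400025333, 0 and 1.01 CPM against 13.6 and 8.898) and neryl diphosphate synthase 1 (PGSC0003DMG400031437, 0 and 0.357 CPM against 4.49 and 6.82), an enzyme of terpene precursors. An RNase H gene (PGSC0003DMG400015911, 0.0184 and 0.0163 CPM against 1.73 and 4.17), a pentatricopeptide protein (PGSC0003DMG400011704, 0.277 and 0 CPM against 3.01 and 4.25) and a pheophytinase-like hydrolase (PGSC0003DMG400023127, 0.0787 and 0 CPM against 2.97 and 1.09) were lower too. So were a zeatin O-glucosyltransferase-like gene (PGSC0003DMG401012694, 0.0734 and 0 CPM against 0.362 and 6.91), the antimicrobial peptide gene snakin-2 (PGSC0003DMG400024474, 0.175 and 0.231 CPM against 12.97 and 12.02) and a cytochrome P450 (PGSC0003DMG400003342, 0.0939 and 0.239 CPM against 12.5 and 6.61).

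Tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and adjusted p was at most 0.025 for the genes called higher or lower at the early stage. Adjusted over the list alone, the counts were as given except 8 lower for monolignol genes, 0 higher for laccases and peroxidases, 7 higher for pattern-triggered signalling and 3 lower for photosynthesis. Median and mean of a list had opposite signs for pathogenesis-related proteins (-0.12 and 0.04), NLR (0.02 and -0.08), MYB (-0.02 and 0.02) and phloem genes (0.09 and -0.06), and the jasmonate list had both above 0 (0.02 and 0.07) with camera pointing down. Leaving out Huangxin 226 turned the sign of the 13S-lipoxygenase (-1.12) and of PGSC0003DMG400011749 (0.35), and leaving out Zhongshuzao 47 that of MSTRG.1852 (0.65). Calls ended without 1 library for PGSC0003DMG400003866 (-0.97 without BF017 early replicate 1 and -0.96 without Huangxin 226 early replicate 3), PGSC0003DMG400006448 (2.71 without Zhongshuzao 47 early replicate 2), PGSC0003DMG401006653 (-1.0 without Zhongshuhong 3 early replicate 2, -0.99 without BF017 early replicate 1 and -0.96 without Zhongshuzao 47 early replicate 1) and PGSC0003DMG400018930 (any of 5 libraries, with -0.77 and adjusted p = 0.42 without Huangxin 226 early replicate 2), and without Zhongshuzao 47 early replicate 2 the Rubisco small chain stood at -4.92.

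At the peak stage, the question was which transcripts separated resistant from susceptible tubers in established disease. The resistant cultivars had lower levels of peroxidase 3 (PGSC0003DMG400005273, -5.73 ± 0.53; 0.0966, 1.47, 28.3 and 13.9 CPM), endochitinase 2 (PGSC0003DMG400026854, -5.44 ± 1.04), a chitin-degrading enzyme, pectinesterase (PGSC0003DMG402017934, 0.04003 and 0.624 CPM against 4.63 and 2.83) and cyclin A3 (MSTRG.11231, -2.40 ± 0.27). Ferulate-5-hydroxylase, which directs lignin towards syringyl units, was higher (3.71 ± 0.64), as were class I small heat shock proteins (PGSC0003DMG400030339, 2.19 ± 0.30; PGSC0003DMG400012619, 1.96 ± 0.42). In all, 2280 genes were higher and 2458 lower in the resistant cultivars, 4738 of 25833, of which 571 and 597 passed with the same sign in all 4 pairs.

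For monolignol biosynthesis 6 of 60 were higher and 16 lower (camera adjusted p = 0.43). Caffeoylshikimate esterase (-1.77 ± 0.16), cinnamate 4-hydroxylase (-1.14 ± 0.16) and p-coumaroyl quinate/shikimate hydroxylase (-1.18 ± 0.32) were lower, and phenylalanine ammonia-lyase PGSC0003DMG402021549 was higher on average (1.33 ± 0.33), with 7140.3, 509, 448 and 1291 CPM and a sign that turned without Zhongshuhong 3 (-0.58). Of 4 further steps that did not pass, 4-coumarate:CoA ligase stood at -0.89 ± 0.52. The acyltransferase PGSC0003DMG400016095 held 46.3, 0, 0 and 0 CPM and the methyltransferase PGSC0003DMG400006448 567, 0.0206, 0 and 0.0649, and neither passed (adjusted p = 1 and 0.19, edgeR with Benjamini-Hochberg adjustment). Flavonoid genes (2 of 13 were higher and 1 lower, camera adjusted p = 0.053) were led by flavanone 3-hydroxylase (PGSC0003DMG400003563, 39.7, 0.117, 0.209 and 0.392 CPM, 2.93 ± 1.15) and flavonoid 3',5'-hydroxylase (30.7, 0.927, 0.697 and 0.838 CPM, 2.80 ± 0.64), both with their highest level in Zhongshuhong 3. Without that cultivar flavanone 3-hydroxylase stood at -1.24.

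Cell division, cell wall and patatin genes were lower and heat shock and photosynthesis genes higher as sets by camera with a preset correlation. For cell division 0 of 69 were higher and 22 lower (adjusted p = 2.1e-06, adjusted p = 0.5 with an estimated correlation). DNA replication licensing factor MCM3 (PGSC0003DMG400008308) stood at -1.75 ± 0.16. For cell wall remodelling 4 of 62 were higher and 20 lower (adjusted p = 0.0037, adjusted p = 0.5 with an estimated correlation). Pectate lyase 5 stood at -4.38 ± 0.42. For patatins 0 of 18 were higher and 9 lower (adjusted p = 0.0016, adjusted p = 0.5 with an estimated correlation), with patatin-like MSTRG.19611 at 0.0663 and 0 CPM against 15.8 and 2.11 and patatin B2 at -2.02 ± 0.38. Patatins share sequence, so reads may be split among copies. For heat shock proteins 17 of 77 were higher and 2 lower (adjusted p = 0.0016, adjusted p = 0.65 with an estimated correlation). For photosynthesis 18 of 66 were higher and 2 lower (adjusted p = 0.046, adjusted p = 0.84 with an estimated correlation), with the chlorophyll a/b binding proteins PGSC0003DMG400008298 (3.17 ± 0.71) and PGSC0003DMG400013413 (2.17 ± 0.53).

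The other lists did not pass by camera, while by fry laccases, suberin, flavonoid, pattern-triggered signalling, NLR, jasmonate, ethylene, WRKY and xylem genes did. For laccases and peroxidases 1 of 49 were higher and 14 lower (camera adjusted p = 0.097), with peroxidase 45 (PGSC0003DMG400029546) at -3.52 ± 0.42. For suberin and wax 0 of 9 were higher and 3 lower (adjusted p = 0.11), with 3-ketoacyl-CoA synthase 11 at -2.88 ± 0.23. For pathogenesis-related proteins 6 of 55 were higher and 8 lower (adjusted p = 0.43), with chitinase 1 (PGSC0003DMG400015523) at -3.87 ± 0.44. For pattern-triggered signalling 9 of 132 were higher and 16 lower (adjusted p = 0.11), with receptor kinase PGSC0003DMG400023614 at -1.81 ± 0.24. For NLR and other resistance proteins 20 of 245 were higher and 36 lower (adjusted p = 0.061). Examples were late blight resistance homologues MSTRG.20372 (-2.19 ± 0.24) and PGSC0003DMG400017086 (-2.07 ± 0.19). For salicylic acid signalling 0 of 19 were higher and 1 lower (adjusted p = 0.91), the gene being EDS1 (PGSC0003DMG400033029, -1.19 ± 0.39), at 37.3 CPM in Huangxin 226 and 5.07 in BF017. For jasmonate 2 of 38 were higher and 7 lower (adjusted p = 0.1). Examples were allene oxide cyclase (PGSC0003DMG401012679, -1.41 ± 0.13), a jasmonate synthesis enzyme, and the repressor TIFY 10b (PGSC0003DMG400022888, -1.29 ± 0.22).

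For ethylene 1 of 31 were higher and 5 lower (camera adjusted p = 0.059), with ethylene receptor 2 (PGSC0003DMG400016284) at -1.59 ± 0.19. For WRKY factors 0 of 42 were higher and 7 lower (adjusted p = 0.072), with PGSC0003DMG400011633 (-3.17 ± 1.14) and PGSC0003DMG400005835 (-1.52 ± 0.52). For MYB factors 3 of 60 were higher and 9 lower (adjusted p = 0.81), with PGSC0003DMG400028119 at -3.68 ± 0.70. For starch 0 of 28 were higher and 2 lower (adjusted p = 0.97). Examples were branching enzyme MSTRG.26324 (0.0534 and 0.0952 CPM against 3.21 and 0.342) and starch synthase PGSC0003DMG401013540 (-1.05 ± 0.12). For sucrose transport and cleavage 3 of 34 were higher and 4 lower (adjusted p = 0.71), with sucrose synthase-like MSTRG.18928 at 2.75 ± 0.28 and sucrose synthase 7 (PGSC0003DMG400016730) at -2.48 ± 0.32. For protease inhibitors 5 of 39 were higher and 4 lower (adjusted p = 0.81), with PGSC0003DMG400002932 at -3.36 ± 0.35 and serine protease inhibitor 5 at -2.98 ± 1.06. Of 4 steroidal glycoalkaloid genes, solanidine glucosyltransferase (PGSC0003DMG400017508) was higher in all 4 pairs (1.32 ± 0.19, 86.4, 58.1, 29.4 and 27.4 CPM). For xylem genes 0 of 5 were higher and 2 lower (adjusted p = 0.65), with xylem serine proteinase 1 at -1.13 ± 0.20, and no phloem gene passed by edgeR or DESeq2 (1 of 4 at an unadjusted p under 0.05), phloem protein 2-like MSTRG.11914 included (-0.62 ± 0.28).

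The largest peak differences of described genes are given likewise. Higher in the resistant cultivars were PGSC0003DMG400003091 (4.21 and 1.63 CPM against 0 and 0), PGSC0003DMG400000534 (1.07 and 3.15 CPM against 0 and 0), raffinose synthase 2 (2.53 and 5.71 CPM against 0.0337 and 0), a kinase similar to rust resistance kinase Lr10 (PGSC0003DMG400020894, 1.75 and 3.88 CPM against 0.0175 and 0) and helicase PGSC0003DMG400027503 (10.3 and 9.402 CPM against 0.492 and 0). The same held for PGSC0003DMG401013133 (2.58 and 6.16 CPM against 0 and 0.0743), a cytochrome c oxidase subunit (PGSC0003DMG400017913, 6.33 and 0.454 CPM against 0.0172 and 0), PGSC0003DMG400010915 (5.73 and 1.39 CPM against 0.155 and 0), PGSC0003DMG400027934 (9.57 and 15.1 CPM against 0.905 and 0.0377) and PGSC0003DMG400006949 (3.17 and 2.46 CPM against 0.0514 and 0.0593). Lower were a miraculin gene (PGSC0003DMG400008536, 0 and 0.0186 CPM against 0.731 and 341), neryl diphosphate synthase PGSC0003DMG400006712 (0 and 0.0186 CPM against 0.243 and 37.7), PGSC0003DMG401012694 (0 and 0 CPM against 0.237 and 6.33), a 2-oxoglutarate-dependent dioxygenase (PGSC0003DMG400011751, 0 and 1.64 CPM against 16.8 and 18.7) and a cytochrome P450 similar to premnaspirodiene oxygenase (PGSC0003DMG400019320, 0 and 0.0186 CPM against 2.93 and 1.61). So were PGSC0003DMG400015911 (0.0167 and 0 CPM against 1.29 and 3.28), PGSC0003DMG400025333 (0 and 0.722 CPM against 10.6 and 9.36), an alpha-mannosidase (PGSC0003DMG400003576, 0 and 0.0939 CPM against 1.26 and 6.46), PGSC0003DMG400011704 (0.0801 and 0 CPM against 3.203 and 1.92) and PGSC0003DMG400025964 (0.0333 and 0.01798 CPM against 3.76 and 2.79).

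Adjusted p in the edgeR quasi-likelihood tests (Benjamini-Hochberg) was at most 0.045 for genes called at the peak. Adjusted over the list alone, the counts were as given except 13 lower for laccases and peroxidases, 1 higher for flavonoids, 14 lower for pattern-triggered signalling, 6 lower for WRKY, 2 higher for sucrose, 17 higher and 1 lower for photosynthesis and 23 lower for cell division genes. Median and mean had opposite signs for monolignol (-0.36 and 0.10), starch (0.29 and -0.11), sucrose (-0.03 and 0.15), steroidal glycoalkaloid (-0.14 and 0.13) and xylem genes (0.09 and -0.33). EDS1 stood at 0.24 without Huangxin 226. Calls ended without 1 library for PGSC0003DMG400007178 (-0.87 without BF017 peak replicate 3), PGSC0003DMG400033029 (-0.57 without Huangxin 226 peak replicate 1), PGSC0003DMG402021549 (0.85 without Zhongshuzao 47 peak replicate 3), PGSC0003DMG401013540 (-0.99 without Zhongshuzao 47 peak replicate 1 and -0.95 without Zhongshuzao 47 peak replicate 2), MSTRG.1852 (-1.90 without Huangxin 226 peak replicate 3, -2.70 without Zhongshuzao 47 peak replicate 3 and -2.73 without Zhongshuzao 47 peak replicate 2), PGSC0003DMG400005835 (any of 4 libraries, with -0.83 and adjusted p = 0.16 without Huangxin 226 peak replicate 1), PGSC0003DMG400011633 (any of 7 libraries, with -2.58 and adjusted p = 0.11 without BF017 peak replicate 3) and PGSC0003DMG400003563 (any of 13 libraries, with 2.71 and adjusted p = 0.18 without Zhongshuzao 47 peak replicate 2). With the call kept, the log2 value (not the fold) moved by over 1.5 times for MSTRG.1852 (-4.95 without Zhongshuzao 47 peak replicate 1). The same held for the chlorophyll a/b binding protein PGSC0003DMG400008298 (6.12 without Huangxin 226 peak replicate 3, 1.91 without Zhongshuzao 47 peak replicate 3).

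The classes rest on 2 cultivars each, so the other ways of setting 2 cultivars against 2 were run alike. Huangxin 226 with Zhongshuhong 3 against the others gave 3325 genes early and 4005 at the peak, 656 and 846 of them in all 4 pairs. Huangxin 226 with Zhongshuzao 47 against the others gave 3786 and 3690, with 823 and 816 in all 4 pairs. Of the genes separating the classes in all 4 pairs, 286 were higher at both stages (10.7 expected of independent lists) and 185 lower at both (8.44 expected), and 0 changed sign. The comparisons at both stages share the same cultivars.

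**Figure D2:**
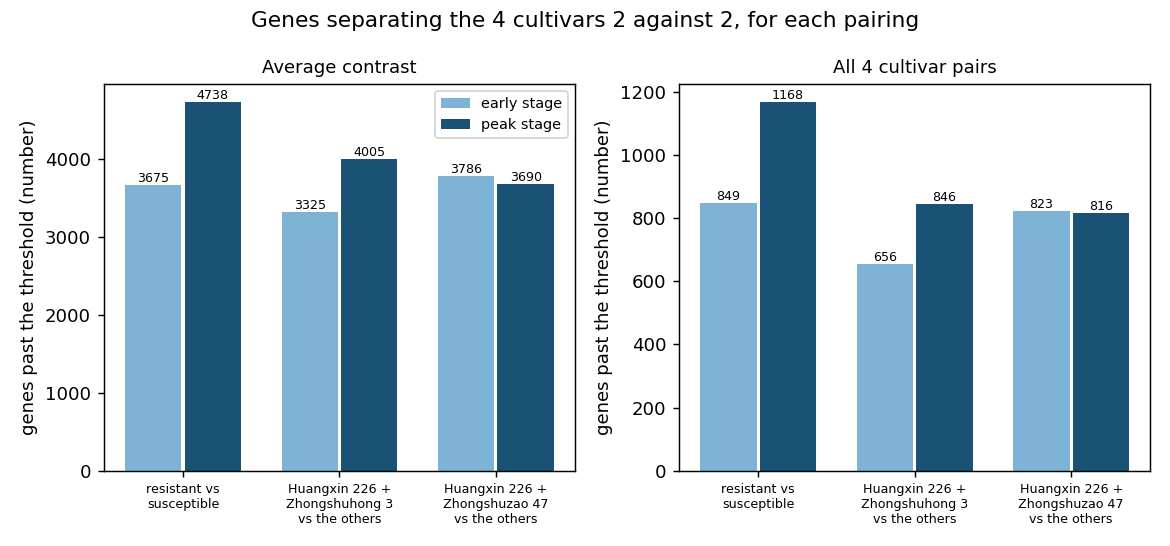
Number of genes past the threshold (vertical axes) for the resistant-susceptible grouping and for both other pairings of the 4 cultivars, for the average contrast (left) and in all 4 cultivar pairs (right), at the early (light) and peak (dark) stage. The classes gave 3675 and 4738 genes, against 3786 early and 4005 at the peak for the higher of the other pairings.

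The next comparison asked what changed in tubers between the early stage and the peak of infection. For flavonoid and anthocyanin genes 0 of 13 were higher and 12 lower (camera adjusted p = 4e-06, adjusted p = 0.14 with an estimated correlation). Chalcone synthase 2 (PGSC0003DMG400019110), the entry enzyme of flavonoid synthesis, went from 564 ± 418 CPM (mean ± SD, n = 3) to 0.136 ± 0.158 in Huangxin 226, from 128 to 0.0388 in BF017, from 308 to 0 in Zhongshuzao 47 and from 1359 ± 398 to 26.1 ± 13.6 in Zhongshuhong 3. For photosynthesis, the green tissue marker, 0 of 66 were higher and 63 lower (adjusted p = 2.9e-16, adjusted p = 0.42 with an estimated correlation). The photosystem II protein PsbS (PGSC0003DMG400017556) fell, with a log2 change of -6.52 ± 0.54 (± SE), and so did vacuolar invertase (PGSC0003DMG400013856), which cleaves sucrose (-4.09 ± 0.36). EIL2 (PGSC0003DMG400008712), a transcription factor of ethylene signalling, rose (1.88 ± 0.10), as did patatin-like MSTRG.19615 (4.45 ± 0.28). On average 1989 genes rose and 3809 fell, 5798 of 25833, and 950 and 1378 of them passed with the same sign in all 4 cultivars.

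**Figure D3:**
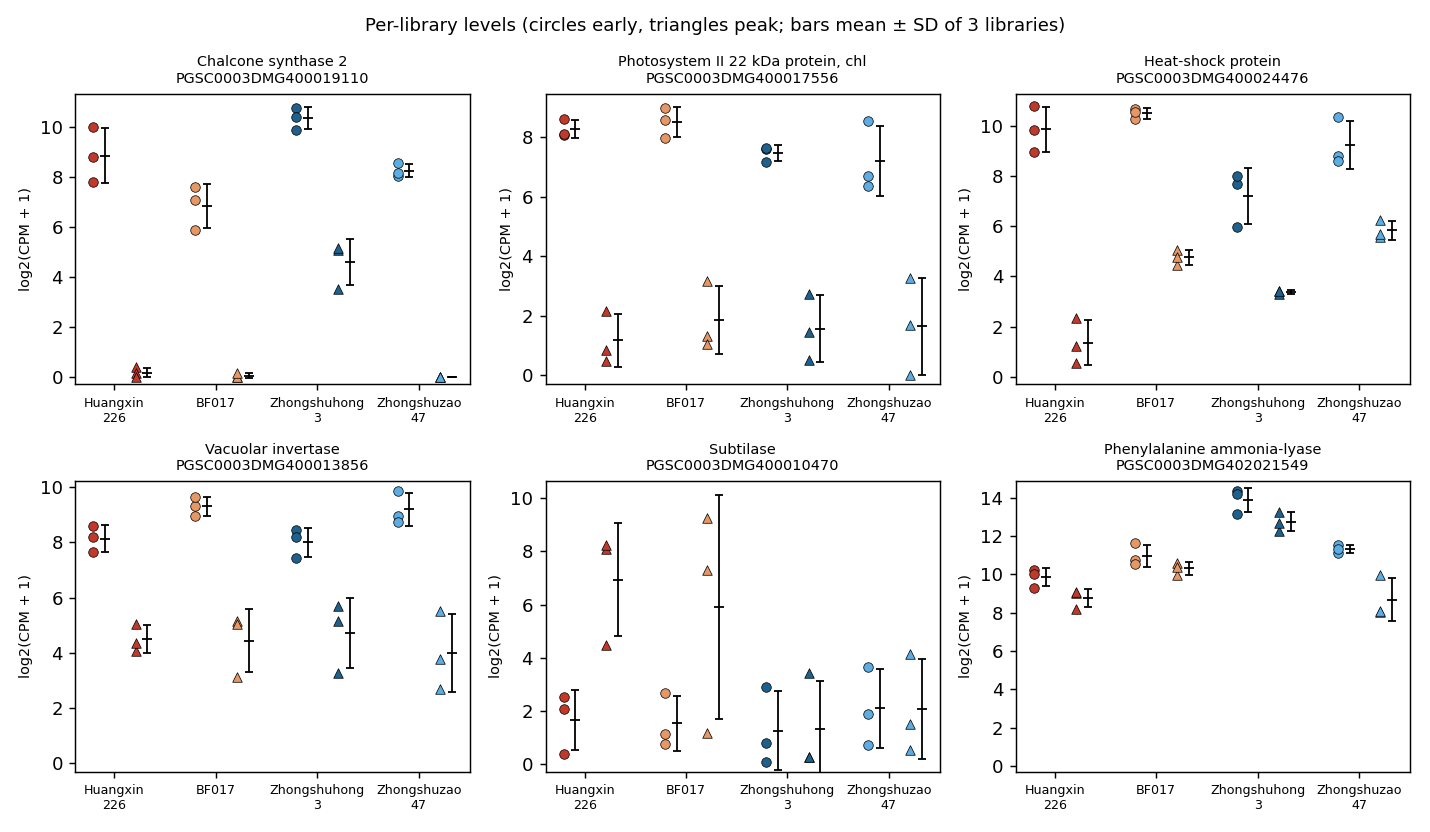
Levels of 6 genes as log2(CPM + 1) (vertical axes) in each of the 24 libraries by cultivar (horizontal), circles early and triangles peak, with bars for mean ± SD of 3 libraries. Chalcone synthase 2 is at 26.1 CPM at the peak in Zhongshuhong 3, and for the subtilase PGSC0003DMG400010470 5 of the 6 susceptible peak libraries lie above every resistant one.

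Chalcone synthase 1B (PGSC0003DMG400029620) held 342, 87.3, 64.7 and 36.2 CPM early against 1.57, 0, 0 and 0 at the peak, chalcone isomerase (PGSC0003DMG400011655) 409.8, 12.4, 32.4 and 24.1 CPM early against 3.05, 0, 0.0175 and 0.0388 at the peak, and an anthocyanin permease (PGSC0003DMG400010166) 834, 10.04, 174 and 35.2 CPM early against 30.9, 0.0186, 0.0514 and 0.221 at the peak. For monolignol biosynthesis 1 of 60 were higher and 31 lower (camera adjusted p = 0.00014, adjusted p = 0.22 with an estimated correlation). Genes that fell were an acyltransferase similar to Pun1 (PGSC0003DMG400025206, 1.09, 2.64, 6.66 and 1.53 CPM early against 0.0367, 0.148, 0.545 and 0.04102 at the peak) and an elicitor-inducible cytochrome P450 (PGSC0003DMG400013684, 8.66, 1.17, 2.16 and 3.22 CPM early against 0.342, 0.0573, 0.547 and 0.183 at the peak). The same held for phenylalanine ammonia-lyase PGSC0003DMG402021549 (-1.34 ± 0.23), 4-coumarate:CoA ligase (-3.12 ± 0.35), cinnamoyl-CoA reductase (-1.31 ± 0.31), ferulate-5-hydroxylase (-2.52 ± 0.40) and caffeic acid O-methyltransferase (-1.26 ± 0.42). The methyltransferase PGSC0003DMG400006448 (2151, 0.425, 6.62 and 1.54 CPM early against 567, 0.0206, 0 and 0.0649 at the peak) and the acyltransferase PGSC0003DMG400016095 (938, 0.0814, 4.803 and 0.961 CPM early against 46.3, 0, 0 and 0 at the peak) fell on average. Of 4 steps that did not pass, cinnamate 4-hydroxylase stood at -0.66 ± 0.11.

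Chlorophyll a/b binding protein PGSC0003DMG400007375 stood at -6.43 ± 0.61. The photosynthesis median was -3.66, -3.41, -2.75 and -1.51 in Huangxin 226, BF017, Zhongshuhong 3 and Zhongshuzao 47 (-3.66, -3.22, -2.63 and -1.48 with genes at 0 in a group set to 3 counts per library). Suberin and wax genes, the periderm marker, also fell (0 of 9 were higher and 5 lower, adjusted p = 0.041, adjusted p = 0.22 with an estimated correlation), among them glycerol-3-phosphate acyltransferase 5 (PGSC0003DMG400006342, 0.255, 83.4, 37.1 and 0.934 CPM early against 0.0167, 2.8, 2.44 and 0.0227 at the peak), a suberin enzyme, and PGSC0003DMG400026127 (-1.22 ± 0.20). For heat shock proteins 8 of 77 were higher and 35 lower (adjusted p = 0.0093, adjusted p = 0.65 with an estimated correlation). Examples were a class IV small heat shock protein (PGSC0003DMG400024476, -5.67 ± 0.34) and Hsp20.1 (-5.39 ± 0.43). For pathogenesis-related proteins 2 of 55 were higher and 17 lower (adjusted p = 0.00065, adjusted p = 0.22 with an estimated correlation), where glucan endo-1,3-beta-glucosidase 11 (PGSC0003DMG400012112) fell (-3.71 ± 0.24) and chitinase 1 (PGSC0003DMG400025352) rose (2.54 ± 0.21). For MYB factors 2 of 60 were higher and 15 lower (adjusted p = 0.041, adjusted p = 0.42 with an estimated correlation). Among them were the morning clock gene LHY (PGSC0003DMG400011294, -3.03 ± 0.12) and MYB48 (PGSC0003DMG400030397, -2.94 ± 0.37).

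Other lists did not pass by camera, while by fry laccases, pattern-triggered signalling, NLR, jasmonate, ethylene, starch, sucrose, cell division, cell wall and xylem genes did. For ethylene 7 of 31 were higher and 2 lower (camera adjusted p = 0.079), including the receptor EIN4 (PGSC0003DMG400028698, 2.19 ± 0.17). For jasmonate 4 of 38 were higher and 9 lower (adjusted p = 0.079). Examples were 12-oxophytodienoate reductase 1 (8.41, 18.5, 25.8 and 43.8 CPM early against 0.02001, 0.8801, 0.675 and 4.42 at the peak), a jasmonate synthesis enzyme, and MYC2 (PGSC0003DMG400005528, -1.48 ± 0.21), its main transcription factor. For salicylic acid signalling 1 of 19 were higher and 3 lower (adjusted p = 0.96), TGA2.2 (MSTRG.2244, 1.24 ± 0.06) rising and TGA factor PGSC0003DMG400027562 falling (-1.18 ± 0.08). For WRKY factors 4 of 42 were higher and 3 lower (adjusted p = 0.46), with PGSC0003DMG401010558 at -1.52 ± 0.18. For pattern-triggered signalling 12 of 132 were higher and 20 lower (adjusted p = 0.6). Examples were RBOHD (-2.64 ± 0.15), which makes superoxide, and a receptor kinase (PGSC0003DMG402026747, 2.11 ± 0.12). For NLR and other resistance proteins 6 of 245 were higher and 34 lower (adjusted p = 0.19), with PGSC0003DMG400041909 (3.76, 0.513, 3.92 and 1.303 CPM early against 0.349, 0, 0.4305 and 0.146 at the peak) and PGSC0003DMG400012458 (-3.21 ± 0.25). For laccases and peroxidases 3 of 49 were higher and 19 lower (adjusted p = 0.1). Examples were peroxidase 12 (PGSC0003DMG401025083, 2.28 ± 0.21) and peroxidase 42 (PGSC0003DMG400016453, -1.83 ± 0.12).

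For sucrose transport and cleavage 2 of 34 were higher and 15 lower (camera adjusted p = 0.058), and the sugar exporter SWEET12 (PGSC0003DMG400032771) held 1.05, 1.36, 4.68 and 17.1 CPM early against 0, 0, 0 and 0 at the peak. For starch 1 of 28 were higher and 4 lower (adjusted p = 0.12). Examples were an ADP-glucose pyrophosphorylase gene (PGSC0003DMG400009026, -4.11 ± 0.41) and branching enzyme 1 (MSTRG.28997, -1.63 ± 0.11). For patatins 1 of 18 were higher and 3 lower (adjusted p = 0.84), with patatin B2 PGSC0003DMG400023699 at -3.27 ± 0.27. For protease inhibitors 4 of 39 were higher and 12 lower (adjusted p = 0.84). Examples were a Kunitz-type inhibitor (PGSC0003DMG400027054, 11.9, 0.0152, 0.616 and 12.9 CPM early against 0, 0, 0 and 0.277 at the peak) and the serpin (5.35, 0.429, 15.5 and 4.69 CPM early against 0.0167, 0.0719, 0.187 and 0.0227 at the peak). For cell division 4 of 69 were higher and 11 lower (adjusted p = 0.39). Examples were cyclin A3 (2.55 ± 0.20) and histone H2B (PGSC0003DMG400007131, -1.52 ± 0.15). For cell wall remodelling 7 of 62 were higher and 21 lower (adjusted p = 0.079), where xyloglucan endotransglucosylase/hydrolase PGSC0003DMG400021877 rose (5.01 ± 0.51) and pectinesterase PGSC0003DMG400002074 fell (-4.85 ± 0.48). Of the 4 steroidal glycoalkaloid genes PGSC0003DMG400011749 fell (-1.62 ± 0.26), and so did the phloem gene MSTRG.11914 (-1.30 ± 0.20). For xylem 0 of 5 were higher and 2 lower (adjusted p = 0.52), with PGSC0003DMG400046654 at -1.17 ± 0.09.

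Among genes with a deposited description that changed in all 4 cultivars, the largest rises were in a miraculin (PGSC0003DMG400010148, 0.0553, 0.09797, 0.227 and 0 CPM early against 2.05, 0.716, 9.87 and 1.095 at the peak) and an amino acid transporter (PGSC0003DMG400043788, 0.441, 0, 0.241 and 0.0205 CPM early against 1.66, 0.886, 3.33 and 3.45 at the peak). Next to PGSC0003DMG400021877 came SAR DEFICIENT 4 (PGSC0003DMG400037424, 3.78 ± 0.47), which acts in pipecolic acid synthesis, and a glucuronosyltransferase (PGSC0003DMG400021784, 3.65 ± 0.47). A Scarecrow-like factor (PGSC0003DMG400026191, 3.16 ± 0.30), pectinesterase 4 (PGSC0003DMG400024049, 3.02 ± 0.22), a B3 domain protein (PGSC0003DMG400000371, 2.87 ± 0.19), a dehydration-responsive AP2/ERF factor (PGSC0003DMG400015889, 2.83 ± 0.23) and a protein phosphatase 2C (PGSC0003DMG400027174, 2.78 ± 0.45) followed. Beside the flavonoid genes and SWEET12, the largest falls were in proline-rich protein 4 (PGSC0003DMG400001631, 17.2, 68.6, 37.1 and 46.1 CPM early against 0.0333, 0.0413, 0.1897 and 0.0421 at the peak), a proline-rich protein DC2.15 (PGSC0003DMG400025972, 8.49, 2.901, 16.1 and 9.57 CPM early against 0, 0, 0.0524 and 0.393 at the peak), a glutathione S-transferase (PGSC0003DMG400027636, 0.806, 6.94, 64.9 and 14.03 CPM early against 0, 0.0799, 0.103 and 0.0183 at the peak), a sterol methyl oxidase (PGSC0003DMG400002156, 4.15, 5.79, 23.2 and 8.51 CPM early against 0, 0.247, 0 and 0.184 at the peak) and a group II intron RNA (ENSRNA049456960, 3.703, 1.85, 1.32 and 2.66 CPM early against 0, 0, 0 and 0 at the peak).

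Within cultivars, 2178 genes rose and 3500 fell in Huangxin 226, 2054 and 3243 in BF017, 2228 and 3911 in Zhongshuhong 3, and 1806 and 2663 in Zhongshuzao 47. The share that rose depended on scaling: in that order it was 38.4, 38.8, 36.3 and 40.4%, with library totals 49.8, 20.2, 46.0 and 19.2%, and on log2(TPM + 1) by limma-trend 61.3, 20.6, 66.2 and 14.5%. The median of all genes moved by 0.11, -0.28, 0.1 and -0.28, and by 0.24, -0.19, 0.3 and -0.29, and the photosynthesis median stayed between -3.7 and -1.51. Adjusted p was at most 0.033 for the genes called (edgeR quasi-likelihood, Benjamini-Hochberg), and adjusted over the list alone the counts were as given except 64 lower for photosynthesis. The salicylic acid list had a median of 0.04 and a mean of -0.11, and the patatin list had both below 0 (-0.20 and -0.11) with camera pointing up. Calls ended without 1 library for PGSC0003DMG400000560 (-0.88 without Huangxin 226 early replicate 2), PGSC0003DMG400016095 (adjusted p = 1 without Zhongshuzao 47 early replicate 2) and PGSC0003DMG400027054 (adjusted p = 1 without Zhongshuzao 47 early replicate 1).

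The last comparison tested whether the change between stages differed between the classes, as the change in the resistant minus that in the susceptible cultivars. Hsp70 fell in the susceptible cultivars, from 11.1 to 0.0524 CPM in Huangxin 226 and from 13.5 to 0.185 in BF017, and went from 1.16 to 0.569 and from 1.603 to 1.76 in Zhongshuhong 3 and Zhongshuzao 47 (adjusted p = 0.00015). The change passed in both susceptible cultivars, where 3 and 9 counts were left at the peak, and on the log2 scale was -1.03 and 0.12 in the others (adjusted p = 0.27 and 0.91). Subtilisin-like protease SBT3 (PGSC0003DMG400010470) reached 199 ± 154 and 256 ± 318 CPM (mean ± SD, n = 3) at the peak in Huangxin 226 and BF017, against 3.32 and 6.36 in the resistant cultivars (-6.04 ± 1.72). Endochitinases 4 (PGSC0003DMG400026855, -6.22 ± 1.5) and 2 (-6.12 ± 1.35) were below 0 too, with 0.286, 1.21, 12.3 and 72.02 CPM for endochitinase 4 at the peak. The interaction passed for 1221 genes, 531 higher and 690 lower, and the other pairings of the cultivars gave 859 and 583.

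For heat shock proteins 28 of 77 were higher and 0 lower (camera adjusted p = 1.4e-11, adjusted p = 0.46 with an estimated correlation). Among them was PGSC0003DMG400024476 (3.50 ± 0.59). For photosynthesis 3 of 66 were higher and 0 lower (adjusted p = 7.7e-08, adjusted p = 0.63 with an estimated correlation). Examples were the PsbP-like gene PGSC0003DMG400024531 (1.80 ± 0.33) and oxygen-evolving enhancer protein 2 (PGSC0003DMG400000926, 1.65 ± 0.52). For patatins 0 of 18 were higher and 9 lower (adjusted p = 8.3e-09, adjusted p = 0.16 with an estimated correlation): patatin-05 (PGSC0003DMG400008749, -4.14 ± 0.71) went from 1059 to 14315 CPM in BF017 and from 7101 to 2523 in Zhongshuhong 3, and patatin-3-Kuras 1 (PGSC0003DMG401017090) was lower too (-4.00 ± 1.06). For monolignol biosynthesis 2 of 60 were higher and 6 lower (adjusted p = 0.025, 0.63 with an estimated correlation). Examples were caffeoyl-CoA O-methyltransferase MSTRG.13851 (-4.81 ± 1.15) and ferulate-5-hydroxylase (4.48 ± 0.80). For ethylene 0 of 31 were higher and 4 lower (adjusted p = 0.025, 0.46 with an estimated correlation). Examples were ACC oxidase 1 (MSTRG.25684, 2.87, 2.36, 0.987 and 1.96 CPM early and 0.050, 0.0899, 32.9 and 1.84 at the peak) and ethylene response factor PGSC0003DMG400010285 (-2.10 ± 0.63).

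For WRKY factors 0 of 42 were higher and 3 lower (adjusted p = 0.0021, 0.63 with an estimated correlation). Examples were PGSC0003DMG400011633 (-5.90 ± 1.60) and PGSC0003DMG400024961 (-1.33 ± 0.40). For cell division 1 of 69 were higher and 6 lower (adjusted p = 0.0021, 0.63 with an estimated correlation). Examples were cyclins PGSC0003DMG400025868 (-2.04 ± 0.43) and PGSC0003DMG400026091 (-1.68 ± 0.30). For NLR and other resistance proteins 2 of 245 were higher and 5 lower (adjusted p = 0.026, 0.63 with an estimated correlation). Examples were PGSC0003DMG401030883 (-1.87 ± 0.38) and PGSC0003DMG400021887 (1.74 ± 0.47).

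The other lists did not pass by camera or fry. For laccases and peroxidases 0 of 49 were higher and 4 lower (camera adjusted p = 0.21). Examples were peroxidases 3 (-3.89 ± 0.67) and 45 (-2.33 ± 0.54). For suberin and wax 0 of 9 were higher and 1 lower (adjusted p = 0.51), the gene being PGSC0003DMG400007373 (-1.45 ± 0.30). For flavonoids 3 of 13 were higher and 1 lower (adjusted p = 0.3). Examples were anthocyanin synthase (-5.02 ± 0.59) and flavonoid 3'-monooxygenase (PGSC0003DMG400024643, 2.96 ± 0.73). For pathogenesis-related proteins 1 of 55 were higher and 6 lower (adjusted p = 0.91), with an endochitinase 4 fragment (MSTRG.6703, 1.04, 3.57, 1.27 and 7.33 CPM early and 0.02001, 0.7298, 10.02 and 70.4 at the peak). For pattern-triggered signalling 2 of 132 were higher and 4 lower (adjusted p = 0.21), with MSTRG.3169 (0.373, 3.12, 3.57 and 0.503 CPM early and 0, 0.745, 0.7997 and 0.396 at the peak). For salicylic acid signalling 0 of 19 were higher and 1 lower (adjusted p = 0.51), the gene being EDS1 (-1.70 ± 0.54). For jasmonate 3 of 38 were higher and 1 lower (adjusted p = 0.082). Examples were a 9S-lipoxygenase (PGSC0003DMG400024689, 1.74 ± 0.38) and an oxophytodienoate reductase (PGSC0003DMG400002952, 1.47 ± 0.36). For MYB factors 1 of 60 were higher and 2 lower (adjusted p = 0.4). Examples were MSTRG.9983 (-1.34 ± 0.37) and the clock gene REVEILLE 1 (PGSC0003DMG400025632, 1.30 ± 0.29).

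For starch 0 of 28 were higher and 1 lower (adjusted p = 0.3), the gene being a starch synthase (PGSC0003DMG402013540, -1.0 ± 0.32). For sucrose 0 of 34 were higher and 1 lower (adjusted p = 0.76), the gene being sucrose synthase 7 (-2.01 ± 0.42). For cell wall remodelling 5 of 62 were higher and 2 lower (adjusted p = 0.27), with MSTRG.10132 (2.71 ± 0.49) and pectate lyase PGSC0003DMG400020156 (2.68 ± 0.60). No protease inhibitor (adjusted p = 0.46), xylem (adjusted p = 0.91), steroidal glycoalkaloid or phloem gene passed by edgeR or DESeq2 (9 of 39, 1 of 5, 2 of 4 and 0 of 4 at an unadjusted p under 0.05), with -0.07 ± 0.39 for cysteine protease inhibitor 1 (PGSC0003DMG400010143), -0.55 ± 0.28 for xylem serine proteinase 1, 0.67 ± 0.26 for solanidine glucosyltransferase and -0.06 ± 0.38 for phloem gene MSTRG.11914. Nor did the most abundant gene of 8 monolignol steps, from -1.91 ± 0.68 for 4-coumarate:CoA ligase to 1.24 ± 0.84 for caffeic acid O-methyltransferase. The acyltransferase PGSC0003DMG400016095 (adjusted p = 1) and the methyltransferase PGSC0003DMG400006448 (adjusted p = 0.49, edgeR) were at or near 0 at the peak in 3 cultivars.

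Next among the interactions above 0 of described genes came a glycerophosphodiester phosphodiesterase (PGSC0003DMG400005228), with 4.17, 8.27, 20.4 and 5.95 CPM early and 1.82, 1.51, 0.362 and 0 at the peak, and a raffinose synthase gene (PGSC0003DMG400018109), with 1.97, 10.04, 32.3 and 6.64 CPM early and 0.901, 3.89, 0.608 and 0.0366 at the peak. A 50S ribosomal protein L14 gene (PGSC0003DMG401005640) held 0, 0.0163, 0.233 and 0.8498 CPM early and 6.698, 1.64, 2.99 and 3.07 at the peak, and PGSC0003DMG400022730, described as a glycerate dehydrogenase with a leucoanthocyanidin dioxygenase as its protein match, 0, 12.98, 10.3 and 12.6 CPM early and 18.6, 15.1, 15.1 and 21.4 at the peak. Below 0 was another SBT3 gene (PGSC0003DMG400010471), with 0.157, 0.467, 0.207 and 0.319 CPM early and 0.0497, 0.0746, 3.38 and 4.22 at the peak. Adjusted p was at most 0.043 for the genes called (edgeR quasi-likelihood, Benjamini-Hochberg). Adjusted over the list alone, the counts were as given except 1 higher and 3 lower for NLR, 0 lower for salicylic acid, WRKY and starch, 4 lower for jasmonate, 1 lower for MYB, 10 lower for patatins, 2 higher for photosynthesis, 7 lower for cell division and 1 lower for heat shock genes. Median and mean had opposite signs for suberin (0.05 and -0.61) and pathogenesis-related genes (0.18 and -0.16), and the sucrose list had both above 0 (0.19 and 0.50) with camera pointing down.

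**Figure D4:**
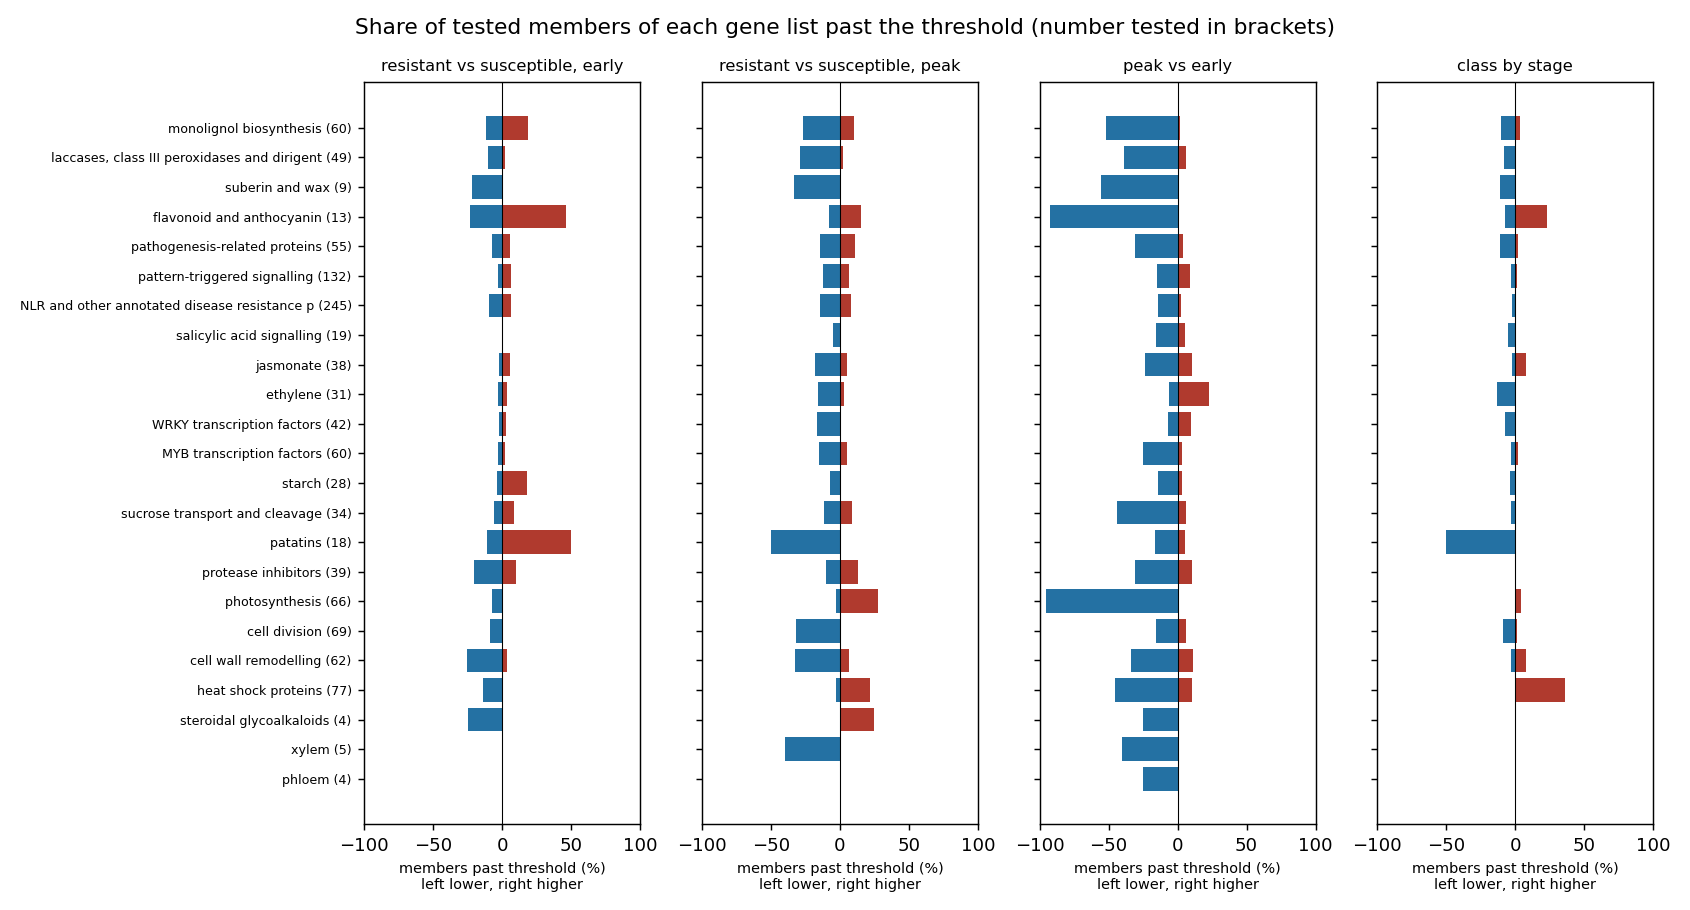
Share of the tested members of each gene list past the threshold (horizontal axes, percent; lower to the left in blue, higher to the right in red; number tested in brackets) in the 4 comparisons. In the peak against early panel 63 of 66 photosynthesis genes were lower, and in the class by stage panel 28 of 77 heat shock genes were higher.

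Without Zhongshuhong 3, 353 of the 1221 interaction genes were called again, and PGSC0003DMG400022730 stood at -0.44 and PGSC0003DMG400024643 at -0.30. Calls ended without 1 library for PGSC0003DMG400010471 (adjusted p = 0.15 without Zhongshuhong 3 early replicate 3), PGSC0003DMG400011633 (-3.56 without Zhongshuzao 47 early replicate 3), PGSC0003DMG400010470 (-4.74 without Zhongshuhong 3 early replicate 3, -5.25 without Zhongshuzao 47 early replicate 2 and -5.18 without BF017 peak replicate 2), PGSC0003DMG400024961 (any of 8 libraries, with -1.14 and adjusted p = 0.068 without Zhongshuhong 3 early replicate 3), PGSC0003DMG400010285 (any of 9 libraries, with -1.61 and adjusted p = 0.071 without Huangxin 226 peak replicate 2) and MSTRG.6703 (any of 10 libraries, with adjusted p = 0.12 without Zhongshuhong 3 early replicate 3). The same held for PGSC0003DMG400000926 (any of 17 libraries, with 1.17 and adjusted p = 0.089 without Zhongshuzao 47 peak replicate 3), EDS1 (any of 17 libraries, with -1.07 and adjusted p = 0.085 without Huangxin 226 peak replicate 1), PGSC0003DMG402013540 (any of 17 libraries, with -0.83 and adjusted p = 0.092 without BF017 peak replicate 3) and PGSC0003DMG401005640 (any of 20 libraries, with adjusted p = 1 without BF017 early replicate 1).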

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

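The interaction tests and the fits without a cultivar or with library totals were planned, while the tests of the genes called again and of the median of all genes in those fits and the splits of whole cultivars were chosen after the interaction had been seen.

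These 10 genes, and 8 lists by camera with a preset correlation (0 with an estimated one, 3 by fry), stand out because their change between stages differed between the resistant and susceptible cultivars on average in the test of that difference. Among genes with a deposited description and a mean of at least 1 CPM, the 5 largest positive interactions were Hsp70 (log2 6.42), the glycerophosphodiester phosphodiesterase PGSC0003DMG400005228 (5.97), the 50S ribosomal protein L14 gene PGSC0003DMG401005640 (5.33), raffinose synthase PGSC0003DMG400018109 (5.20) and PGSC0003DMG400022730 (5.17). The 5 largest negative ones were endochitinase 4 (-6.22), endochitinase 2 (-6.12), the subtilases PGSC0003DMG400010470 (-6.04) and PGSC0003DMG400010471 (-5.81) and the WRKY gene PGSC0003DMG400011633 (-5.90). The 5 positive values and that of PGSC0003DMG400010471 are of genes with 3 or fewer counts in a group, depend on the prior count and are not bounds. Without Zhongshuhong 3 PGSC0003DMG400022730 stood at -0.44. Leaving out any 1 of 20 libraries ended the call of PGSC0003DMG401005640 (1.79 without BF017 early replicate 1), any of 3 that of PGSC0003DMG400010470 (-4.74 without Zhongshuhong 3 early replicate 3) and 1 each those of PGSC0003DMG400010471 (-5.12 without the same library) and PGSC0003DMG400011633 (-3.56 without Zhongshuzao 47 early replicate 3).

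Among lists, camera gave an adjusted p of 1.4e-11 for heat shock proteins and 7.7e-08 for photosynthesis, whose medians fell less in the resistant cultivars. Patatins (8.3e-09), cell division (0.0021), WRKY factors (0.0021), monolignol biosynthesis (0.025), ethylene (0.025) and NLR proteins (0.026) pointed down. With an estimated correlation the adjusted p was 0.16 for patatins, 0.46 for heat shock and ethylene genes and 0.63 for the other 5 lists.

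The 1221 interaction genes may rest largely on 1 cultivar: without Zhongshuhong 3, 353 of them (28.9%) were called again, against 669 (54.8%) without Huangxin 226, 617 (50.5%) without BF017 and 893 (73.1%) without Zhongshuzao 47. Leaving out any cultivar also removes 6 libraries, and the share without BF017 lies close to the bound of 50% that the test had set. With library totals the median interaction of all genes was -0.000917, and a few abundant genes taking the counts would move all genes alike, which argues against them as the whole explanation. The classes gave 1221 genes and the higher of the other pairings of whole cultivars 859, and 3 pairings are too few for a share under 0.05. A difference between the classes in their response to infection and a trait of Zhongshuhong 3 unrelated to its class both stay open, as these 4 cultivars cannot separate them.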

How the results depend on the processing

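The restriction to reference gene models and the stage comparison without a cultivar were chosen after the results had been seen; every other setting here was planned. Of 256 named gene and comparison pairs, 220 were past the threshold, and 139 of these stayed past it with the same sign in all settings; 79 lost the call somewhere (407 of 9122 values) and 11 changed sign in 12 values, 11 of them without a cultivar and 0 without a library. Of the other 36 pairs, 16 passed somewhere (53 of 1504 values). Size factors of DESeq2 and library totals ended 0 and 2 of the named calls, and library totals took the share of higher genes between stages from 34.3 to 29.1% on average, from 38.4 to 49.8% in Huangxin 226 and from 40.4 to 19.2% in Zhongshuzao 47. Leaving out 1 library ended a call in 25 pairs (149 values) and moved the fold by over 1.5 times in 67 pairs. Depth limits what can be said of genes near the floor of 3 counts. The cause of each change below was not tested unless the setting itself gives it (fewer genes, libraries or cultivars, or another threshold).

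Counts moved by over 1.5 times as follows. The filter of 1 CPM in 12 libraries gave 1938 genes for resistant against susceptible early, 2684 at the peak, 532 in all 4 pairs early and 3758 between stages. Reference gene models alone gave 2055 and 3088, and 422 and 768 in all 4 pairs. A fit with the classes only gave 1256 early and 1719 at the peak. It counts differences between cultivars as spread and also tested fewer genes (22146 and 21230). An adjusted p under 0.01 gave 552 and 721 in all 4 pairs and 549 for the interaction. Without the fold threshold there were 9151 early, 11515 at the peak, 1850 in all 4 pairs at the peak, 16342 between stages and 4457 in all 4 cultivars, 11204, 10990, 11859 and 9893 in Huangxin 226, BF017, Zhongshuhong 3 and Zhongshuzao 47, and 3562 for the interaction. On log2(TPM + 1) limma-trend gave 2111 early, 2386 at the peak, 771 in all 4 pairs at the peak, 3137 between stages and 713 for the interaction, and without a TPM filter 2281, 2552, 3144 between stages, 1480 in all 4 cultivars and 708. With only 2 pairs left, those in all remaining pairs numbered 2243 early and 3196 at the peak without Huangxin 226, 2230 and 2831 without BF017, 2253 and 2689 without Zhongshuhong 3, and 3143 and 3740 without Zhongshuzao 47. The interaction gave 679 genes without Zhongshuhong 3 and 2193 without Zhongshuzao 47.

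Leaving out each library gave 3538 to 3828 genes early, 4573 to 4894 at the peak, 731 to 880 and 1009 to 1188 in all 4 pairs, 5842 to 6153 between stages, 2104 to 2357 in all 4 cultivars, 4921 to 5984 in Huangxin 226, 4622 to 5458 in BF017, 5380 to 6255 in Zhongshuhong 3, 3892 to 4604 in Zhongshuzao 47 and 955 to 1285 for the interaction. The replicate block gave 3629 genes early, 4678 at the peak, 836 and 1129 in all 4 pairs, 5748 between stages, 2313 in all 4 cultivars, 5622, 5218, 6050 and 4425 in the cultivars in the order above and 1159 for the interaction. Replicate numbers do not pair the libraries: deviations of same-numbered libraries had a mean r of 0.00744 across genes, against -0.00363 for other numbers, 2 of 12 pairs within a cultivar were over 0.1, and 9 of 24 libraries correlated best with their own number. The block ended the interaction calls of PGSC0003DMG401005640, PGSC0003DMG400033029, PGSC0003DMG400010285 and PGSC0003DMG402013540, let 4-coumarate:CoA ligase PGSC0003DMG400003155 pass early, and changed no other named call.

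Signs turned without Zhongshuhong 3 early for PGSC0003DMG400022746 (-1.66), PGSC0003DMG400000425 (-2.01), PGSC0003DMG400006448 (-2.89), PGSC0003DMG400016095 (-4.62), PGSC0003DMG400003155 (-0.31), PGSC0003DMG400027892 (0.20), PGSC0003DMG402030469 (0.17) and PGSC0003DMG400007178 (0.27), at the peak for PGSC0003DMG400003563 (-1.24), PGSC0003DMG402021549 (-0.58), PGSC0003DMG400000560 (-0.51) and PGSC0003DMG400016095 (0.00), and in the interaction for PGSC0003DMG400022730 (-0.44), PGSC0003DMG400024643 (-0.30), PGSC0003DMG400010143 (1.66) and PGSC0003DMG400005001 (-0.06). Without Huangxin 226 they turned early for PGSC0003DMG400032155 (-1.12), PGSC0003DMG400011749 (0.35), PGSC0003DMG400016951 (-0.07) and PGSC0003DMG400028521 (-0.21), and at the peak for PGSC0003DMG400033029 (0.24) and PGSC0003DMG400003155 (0.23). Without Zhongshuzao 47 they turned early for MSTRG.1852 (0.65), PGSC0003DMG400016951 (-0.24) and PGSC0003DMG400028521 (-0.09), at the peak for PGSC0003DMG400028521 (-0.05), between stages for PGSC0003DMG400007178 (0.06) and in the interaction for MSTRG.11914 (0.11). Without BF017 they turned at the peak for PGSC0003DMG400000560 (-0.37), between stages for PGSC0003DMG400005001 (0.01) and in the interaction for PGSC0003DMG400010143 (0.93), PGSC0003DMG400028521 (-0.08) and PGSC0003DMG400005001 (-0.11). With the classes only PGSC0003DMG400032155 stood at 0.00 early. By limma-voom PGSC0003DMG400000560 stood at -0.18 at the peak and PGSC0003DMG400028521 at -0.03 in the interaction, where TPM gave PGSC0003DMG400028521 -0.08 (-0.10 with a pseudocount of 0.1), PGSC0003DMG400005001 0.00 and PGSC0003DMG400016095 -0.51. Leaving out single libraries took PGSC0003DMG400000560 from -0.35 to 0.54 at the peak, PGSC0003DMG400016951 from -0.09 to 0.26 and PGSC0003DMG400028521 from -0.17 to 0.39 early, and in the interaction PGSC0003DMG400028521 from -0.18 to 0.60, PGSC0003DMG400010143 from -0.30 to 0.06, PGSC0003DMG400005001 from -0.03 to 0.07 and MSTRG.11914 from -0.31 to 0.11. Of 21 lists 4, 13, 17 and 3 (heat shock, patatins and ethylene) passed by fry early, at the peak, between stages and in the interaction, against 3, 5, 7 and 8 by camera. By fry the direction differed from camera for salicylic acid (adjusted p = 0.9) and starch (0.72) at the peak and for salicylic acid between stages (0.52), none of which passed.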

Other observations

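The Gene Ontology enrichments, the tests from library totals (a planned fit), the test of the periderm list and the splits of whole cultivars were chosen after the results had been seen, while the clock gene, near-zero and library split tests were written before theirs.

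Terms were tested whether or not they overlapped the fixed lists, by 1-sided exact tests over 1313 terms in 20428 annotated genes (Benjamini-Hochberg). Genes that rose in all 4 cultivars between stages held 50 ribosome genes (17.5 expected, adjusted p = 3.3e-08). Among genes higher in the resistant cultivars in all 4 pairs early, 26 belonged to DNA integration, a term of mobile elements (4.4 expected, adjusted p = 5.1e-10), and 16 to monooxygenase activity (3.51 expected, adjusted p = 0.00036), a term that holds cytochrome P450 enzymes and that was also enriched among the lower ones (13, 3.79 expected, adjusted p = 0.036). Of those higher in all 4 pairs at the peak, 19 were monooxygenases (5.12 expected, adjusted p = 0.00071), and of those lower 19 were glycosyl bond hydrolases (4.51 expected). Interaction genes with a lower change in the resistant cultivars held 23 of defence response to fungus (7.57 expected, adjusted p = 0.00083), and those with a higher change 23 of response to heat (1.78 expected).

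Of 66 photosynthesis genes 63 were lower at the peak. With library totals the list's upper quartile was -1.8 and the median of all genes -0.12, which argues against a few abundant genes taking the counts, since that would lower all genes alike. The 20 annotated evening clock genes had a median change of 0.24 (6 higher, 2 lower, and -0.03 in Zhongshuzao 47). The 6 morning ones had -1.15 (4 lower). These medians go with another time of day at sampling. Evening members went both ways, so it stays open, a reading set after the value was seen. A smaller share of green outer tissue stays open as well, since the periderm list had a median above 0 in 0 of the 4 cultivars. A change of infected tissue between stages was not tested apart from these, as stage, tuber age and sampling time go together.

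Of the 471 genes separating the classes in all 4 pairs at both stages, 112 lay under 0.1 CPM in both cultivars of a class at both stages, 72 of them near 0 in the susceptible cultivars. The other pairings gave 109 of 375 and 145 of 452, so alleles or genes absent from a cultivar and unrelated to the class are a candidate explanation that has the values it needs. All 112 were called again at both stages with library totals alone, but genes chosen for such a separation would be, so this decides nothing about normalization. A link with resistance stays untested for any of them.

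Library splits used limma-trend with the classes or stages alone. The real split gave the most genes of 100 early (1672, highest other 2), at the peak (2422, highest other 3), between stages (5273, highest other 2039) and in all 4 cultivars (2352, highest other 0), 1 of 100 in each. For stages this excludes chance labels of libraries, not of samplings. Class splits break up cultivars, so chance for whole cultivars stays open. Within a cultivar 10 splits are too few for a share under 0.05. Real ones gave 4798, 4962, 5368 and 3940 genes in Huangxin 226, BF017, Zhongshuhong 3 and Zhongshuzao 47, the highest others 1, 1, 1 and 0. The 3 pairings of whole cultivars are also too few: the classes gave 3675 genes early (highest other 3786, so 2 of the 3 pairings gave as many), 849 in all 4 pairs (823), 4738 at the peak (4005) and 1168 in all 4 pairs (846).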
